A study of Bos taurus with 40 samples.

How the data were processed

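RNA was measured in bovine granulosa cells, cumulus cells, ooplasm biopsies and whole oocytes, and bisulfite-converted DNA in first polar bodies, with 4 samples per group. Per the labels' protocols, RNA libraries were made with SMART-Seq HT and Nextera XT kits, and polar body DNA with an EpiTect bisulfite kit and an NEBNext kit. Per the submitters' processing notes, Trim Galore, cutadapt, STAR and featureCounts were used for RNA and Bismark and methylKit for DNA. Their versions, the aligner settings and the genome build are not given in the sources used here.

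The authors deposited a whole-number count per row for each RNA library, in 4 tables of 59051 rows, and these were used as deposited. The rows hold 27607 Ensembl identifiers, 22227 NONCODE identifiers, 7848 LOC identifiers and 1369 symbols. A RefSeq gene table of the ARS-UCD2.0 assembly was used for names only, and matched 5258 LOC identifiers, 1105 of them to a current symbol. In all 2474 rows carried a symbol. Ensembl rows stay unnamed, so the named genes come from a minority of rows and most well-known markers could not be looked up. The polar body table lists 34020 positions with 24 columns of values whose headings carry numbers alone. Those 24 columns could not be tied to samples by name and were not used.

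Libraries took their group from the labels. Granulosa and biopsy libraries share oocyte labels, and the series text ties the granulosa cells to the oocyte of the same follicle, so these labels pair them. Their deviations from the group means correlated at -0.0202 to 0.186 in the 8 same-label pairs (mean 0.0669), across genes, which are not independent replicates. The 56 different-label pairs covered almost the same range, -0.192 to 0.182 (mean -0.0097). This check therefore does not show the pairing, which rests on the labels. In the matched set the same-number values were 0.173 to 0.261 in the 4 pairs, each over the 0.1 fixed as the bound for pairing, and the numbers were taken as pairs. Biopsy 6 with oocyte 16 (0.173) and biopsy 16 with oocyte 6 (0.172) lay over it too, so the check does not tell pairs 6 and 16 apart, and the other different-number values were 0.0131 or lower. The cumulus columns carry the fate but not the title number. Pairs of libraries differed by more than counting noise in every group, with a chi-square per degree of freedom of 5.03 or more. Nothing states that all samples came from separate animals, so p-values measure only the spread between these samples. Counting intervals and floors cover counting error only.

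Each comparison was fitted on its own libraries. Rows were filtered with filterByExpr, scaled by TMM and tested with edgeR 4.0.16 (robust quasi-likelihood F tests, R 4.3.3), and a Benjamini-Hochberg adjusted p under 0.05 was called. The difference between granulosa cells and biopsies in the contrast of the fate groups was the interaction term of a joint fit. DESeq2 1.42.0 (Wald test) was the other tool. It was run on every row with a count, without filterByExpr, so its calls come from more rows than those of edgeR. CPM are TMM-scaled counts at a library total of 1000000 unless stated, and errors are SD over 4 libraries. The summed chemosensory level, the RN18S1 and XIST values of granulosa library B20 and the shares of excess counts used library totals without TMM. A row was detected at 5 counts or more. Single values were compared by exact two-sided permutation over the 70 assignments of the libraries, where the smallest possible p is 0.0286. Python 3.11.15, pandas 2.3.3 and matplotlib 3.10.9 were used for tables and figures.

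Gene sets with at least 5 tested members were tested with camera of limma 3.58.1 at a preset correlation of 0.01, beside an estimated correlation and fry. Of 29 lists with 934 symbols, written before the data were examined, 22 rows were matched, and the imprinted genes alone, with 9 rows, reached 5. A further 12 families defined by symbol were written after a first fit had been seen, and the chemosensory receptors among them after their values had been seen. The comparisons, thresholds, most alternatives and the rule for named genes were fixed before the data were examined. The rule takes the 10 symbol rows of smallest p in each direction past the threshold, or, where fewer than 5 pass, the 5 of smallest p whether or not they pass. It adds up to 4 members of each fixed list past the threshold and marker genes, of which H1FOO had a row under its symbol. Where a group held 1 to 3 counts, the ratio is given with a 95% counting interval. A group at 0 is set to a floor of 3 counts per library.

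The tests were tried on simulated counts with 200 changed genes in 5 draws, once with folds of 2, 4, 8 and 32 and once without 32. With all folds, the percent recovered at 2-fold, 4-fold, 8-fold and 32-fold was, as lowest to highest draw, 0 to 12, 24 to 36, 50 to 64 and 68 to 88 in the biopsy simulation (19796 genes or more). In the granulosa simulation (21877 genes or more) it was 0, 4 to 8, 28 to 42 and 80 to 92. In the cumulus simulation (15233 genes or more) it was 78 to 88, then 98 to 100 at each larger fold. In the matched simulation (17548 genes or more) it was 0 to 4, 18 to 58, 64 to 80 and 82 to 92. In the interaction simulation (26714 genes or more) it was 0, 0 to 6, 14 to 20 and 42 to 62. Without the 32-fold genes, 8-fold genes were recovered at 42.4 to 59.1% in the biopsy simulation, 0 to 27.3% in the granulosa simulation, 98.5 to 100% in the cumulus simulation, 63.6 to 72.7% in the matched simulation and 6.06 to 12.1% in the interaction simulation. False calls numbered 0 to 20 per draw. Alternatives covered scaling, tool, filter, threshold, each library left out, the letter of the oocyte label and the pairing.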

Results

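Single bovine oocytes were followed after in vitro maturation and grouped by whether they reached the blastocyst stage or stopped at cleavage. RNA was counted in granulosa cells, cumulus cells and ooplasm biopsies, with 4 libraries per fate and cell type, and in 4 further biopsies matched by number to 4 whole oocytes. In units of 1000000 counts, libraries held 9.88 to 17.7 for granulosa cells, 7.96 to 9.59 for cumulus cells, 16.8 to 22.6 for biopsies and 13.4 to 23.8 for the matched set.

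In granulosa cells, the somatic cells lining the follicle, TTLL11, a tubulin polyglutamylase, rose in the blastocyst group to 63.4 ± 42.5 CPM against 3.5 ± 2.0 in the cleavage group (log2 4.18, SE 0.66, n = 4). ANOS1, a secreted matrix protein, rose to 52.9 CPM (SD 36.95) against 3.67 ± 1.98, and FAM160A1, a trafficking factor, to 69.3 ± 43.5 CPM against 7.86 ± 3.50. SLC22A14, an organic ion transporter family member, had 432 counts against 1, a ratio of 370 with an interval of 66.1 to 14654. MCHR2, a receptor for melanin-concentrating hormone, had 510 counts against 1, a ratio of 437 (78.1 to 17294). KIAA1210, C16H1orf158, an axonemal protein, ERICH6B, ITIH6 and HRASLS5, a phospholipid-modifying enzyme, rose as well, and each of these 10 genes lay above the cleavage mean in 4 of 4 libraries (edgeR quasi-likelihood adjusted p = 0.0116). The 10 were chosen by smallest p in this same contrast, so that count is no separate evidence. Each was highest in library B20 and next highest in D27: TTLL11 stood at 117 and 77.8 CPM there, against 25.4 in B21 and 33.3 in D24. C5H12orf57 fell to 13 ± 6.95 CPM against 45.5 ± 8.67 (edgeR adjusted p = 0.0367), FAM200B to 6.59 ± 2.96 against 40.2 ± 36.7, where B23 (73.9) and D10 (70.1) were high and B14 (8.09) and D29 (8.85) lay within the blastocyst range of 3.02 to 9.19 (edgeR adjusted p = 0.0399), and ZNF845, a zinc finger protein, to 15.6 ± 5.74 against 38.0 ± 5.64 (edgeR adjusted p = 0.0418). These 3 calls ended with library totals as the only scaling and without D27, among other alternatives. With the chemosensory level as a covariate, chosen after seeing the data, C5H12orf57 turned to a log2 fold change of 0.17. In that fit the median of all rows was 0.86, against 0.10 in the main fit, so the change of sign is not shown to be particular to this gene. LRRN2 and HEXDC did not pass.

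In all, 4884 of 22934 rows rose in the blastocyst-group granulosa cells and 80 fell (edgeR quasi-likelihood, adjusted p under 0.05). The DESeq2 Wald test, run without the filter on low counts, called 11467 of 35243 rows. The edgeR count was 3162 without B20, 2482 without D27 and 8131 without B23 of the cleavage group. The number of rows that fell was 42 with DESeq2 size factors, 11 with library totals, 50 with the label letter as a covariate, 378 with the DESeq2 Wald test and 594 at adjusted p under 0.10. It was 456 without B21, 153 without D24, 19 without D27, 36 without B14, 181 without B23, 17 without D10 and 33 without D29. Without both B20 and D27, an alternative chosen after seeing the data, edgeR called 0 rows, with 4602 at an unadjusted p under 0.05. In that fit of 2 against 4 libraries TTLL11 had a log2 fold change of 3.15 and ANOS1 of 2.81, so the lost calls do not show that the differences were gone. The share of rows called higher was 28.2% under 1 CPM and 3.11% over 100 CPM. The median log2 fold change of all rows was 0.10 with TMM, 0.48 with DESeq2 size factors and 0.70 with library totals. Among rows without a name, ENSBTAG00000020141 rose by 8.25 and ENSBTAG00000007595 fell by 1.80 on the log2 scale.

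Chemosensory receptors, the odorant, taste and vomeronasal receptors of sensory cells, rose in granulosa cells of the blastocyst group in 31 of 51 rows, with 50 positive and a median log2 fold change of 4.32. These 51 are the rows with enough counts out of 1027. Rows with a count were more frequent in the blastocyst group, so the filter favoured receptors high there. Over all 1027 the ratio of mean CPM was 10.96, here per library total without TMM and so on another scale than the median. Receptors of such a large family can share reads, which was not tested here, so the level of any single receptor is uncertain. Collagens rose in 6 of 13 rows: COL6A6 to 34.8 ± 27.1 against 1.45 ± 1.12 CPM, COL19A1 to 106 ± 87.7 against 3.57 ± 5.43 CPM, and COL24A1, COL25A1, COL28A1 and COL22A1. COL4A4, a basement membrane chain, stood at 364 ± 250 against 938 ± 183 CPM and did not pass. The ubiquitin ligases MARCH1, MARCH4, MARCH10 and MARCH11, 4 of 11 members of the MARCH family, rose, as did 3 of 12 tRNA loci. Of all tested symbol rows 25.6% were called higher and of all LOC rows 34.7%, so these 2 counts lie near the general share. Of 6 matricellular CCN proteins, WISP1 (4.67 ± 0.874 against 0.300 ± 0.477 CPM) and WISP2 (3.54 ± 1.35 against 0.0858 ± 0.129 CPM) rose, whereas the more abundant CTGF (16.4 ± 14.5 against 99.9 ± 92.4 CPM) and CYR61 (60.4 CPM against 224, SD 61 and 231) had lower means and did not pass. None of the 18 aminoacyl-tRNA synthetases, which charge tRNAs, passed, and their median was -0.70 with TMM, -0.47 with DESeq2 size factors and -0.23 with library totals. Histones passed in 0 of 37 rows, with medians of -0.58, -0.39 and -0.13 under these scalings. The medians of septins (-0.26), zinc finger proteins (-0.31) and RNA tailing factors (-0.33) turned positive under both other scalings. With TMM, the medians of all rows at 10 to 30, 30 to 100 and over 100 CPM were -0.17, -0.64 and -0.91. A negative median of an abundant family, such as the synthetases, is therefore not shown to be particular to it.

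By camera against other rows, adjusted p was 6.35e-11 for chemosensory receptors, 0.00067 for aminoacyl-tRNA synthetases, 0.000961 for histones, 0.00901 for tRNA loci, 0.0266 for zinc finger proteins and 0.136 for collagens. None of these families held, each with adjusted p = 0.532 with an estimated correlation. All symbol families were written after a first fit had been seen, and the chemosensory receptors after their values. Their p-values here are therefore descriptive only. Camera adjusted p was 0.844 for both CCN proteins and MARCH ligases, 0.445 for septins and 0.328 for RNA tailing factors. By fry, which tests whether a family moves one way and not against other rows, adjusted p was 0.000881 for chemosensory receptors, 0.0106 for tRNA loci, 0.0119 for both collagens and CCN proteins, 0.0305 for MARCH ligases, 0.0959 for aminoacyl-tRNA synthetases and 0.264 or more for the other families. Of the imprinted genes 1 of 7 rose, also 1 adjusted over the list alone: MEG8, a maternally expressed noncoding RNA, at 17.0 ± 11.6 against 1.33 ± 1.33 CPM (edgeR adjusted p = 0.0264). MEG3, from the same cluster, H19 and XIST did not pass. The list's median of 1.28 and mean of 0.78 were positive, and camera showed no shift against other rows (p = 0.969, and adjusted p = 0.969 with an estimated correlation). By fry, p was 0.0865 for a move upward and 0.000577 in its mixed form, which counts changes in either direction.

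The granulosa libraries of the blastocyst group had 27546 ± 1170 detected rows against 19465 ± 1762 (exact permutation p = 0.0286, n = 4). Chemosensory receptor rows with a count made up 52.7 ± 20.7% against 5.70 ± 5.11% (exact permutation p = 0.0286, n = 4). H1FOO, the oocyte linker histone, stood at 12.9 ± 7.16 CPM against 2.02 ± 3.15 and did not pass (edgeR adjusted p = 0.0877). B20 had the lowest level of the 8 granulosa libraries for the ribosomal RNA RN18S1 (333 CPM) and for XIST (140 CPM), both without TMM. The 10 most abundant rows took 6.70 ± 3.74% of counts against 12.3 ± 1.42% (exact permutation p = 0.0286, n = 4).

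**Figure D1:**
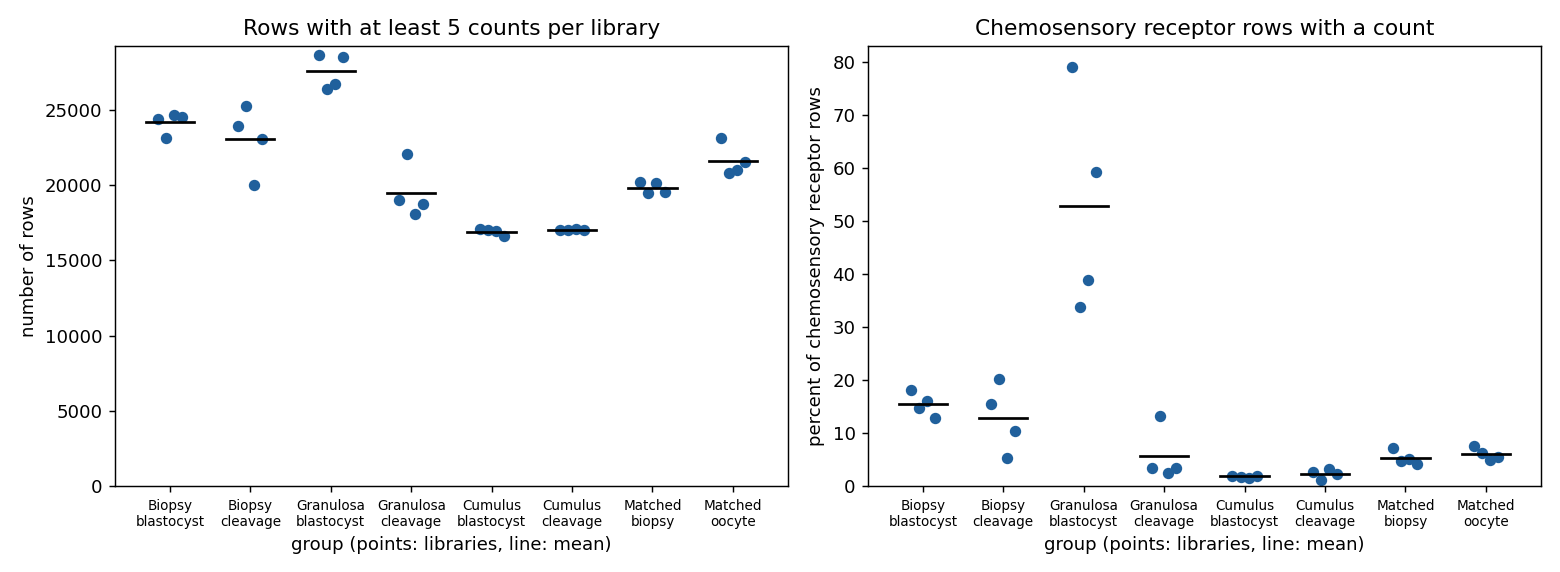
Rows with at least 5 counts (left) and percent of chemosensory receptor rows with a count (right) in each library (points), with the mean of each group of 4 (line). Granulosa libraries of the blastocyst group held 26373 to 28629 detected rows and those of the cleavage group 18065 to 22039.

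In cumulus cells, the somatic cells around the oocyte, no gene passed with edgeR, and the genes of smallest p differed by small folds. H1FX, a linker histone, stood at 116 ± 6.02 CPM in the blastocyst group against 83.5 ± 8.11 (log2 0.47, SE 0.08, edgeR quasi-likelihood adjusted p = 0.0751). KIAA1551, a factor in silencing of retroelements, stood at 556 ± 67.8 against 896 ± 143 CPM (log2 -0.69), and FAM208A, a subunit of the HUSH silencing complex, at 82.7 ± 11 against 115 ± 5.62 CPM (log2 -0.47, edgeR adjusted p = 0.103 for both). XIST, the RNA of X inactivation, stood at 250 ± 51.1 against 404 ± 52.4 CPM (edgeR adjusted p = 0.134). DGKH, a lipid kinase, and TROVE2, an RNA-binding protein, had lower means in the blastocyst group, and TMEM8A, FAM227B, ASNA1 and the splicing factor SNRNP70 higher ones. In all 0 of 15410 rows passed with edgeR, and 2249 had an unadjusted p under 0.05 (955 higher, 1294 lower). The DESeq2 Wald test called 159 of 26278 rows (27 higher, 132 lower), H1FX, KIAA1551, FAM208A, DGKH, TROVE2 and XIST among them. Without a filter on low counts edgeR called 22 higher and 161 lower. The edgeR count was 7 without blastocyst library 12 and 3 without cleavage library 7, and 10 at adjusted p under 0.10. No symbol family passed with camera. Detected rows numbered 16910 ± 224 against 17046 ± 31.4 (exact permutation p = 0.257, n = 4). After thinning to the smallest total the difference was -0.5 rows (exact permutation p = 1). It was -29.75 without blastocyst library 12, and -203.75 without blastocyst library 9 (exact permutation p = 0.0286).

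In ooplasm biopsies no gene passed with edgeR between fates. The olfactory receptors OR4X2B (16.5 ± 14.6 CPM in the blastocyst group against 0.852 ± 0.933), OR4X16 (18.2 ± 10.7 against 3.50 ± 1.89) and OR4X2 (5.08 ± 4.04 against 0.216 ± 0.202) had the smallest p of the genes with a higher mean, but reads shared within this receptor group, not tested here, leave their separate levels uncertain (edgeR quasi-likelihood adjusted p = 0.600 for OR4X2B). SLC5A3, an inositol transporter, stood at 75.8 ± 11.4 against 40 ± 1.48 CPM, and HIST1H2BB, a core histone, at 88.3 ± 32.3 against 41.6 ± 4.32 CPM. FAM200B stood at 14.5 ± 5.46 against 112 ± 127 CPM, C5H12orf45 at 36.2 ± 14.6 against 84.4 ± 11.7 CPM, the linker histone HIST1H1A at 155 ± 35.9 against 276 ± 58.2 CPM, the collagen COL24A1 at 51.9 ± 6.40 against 101 ± 33.5 CPM and VARS, which charges valine tRNA, at 7.87 ± 0.730 against 21.8 ± 8.74 CPM. H1FOO, the oocyte linker histone, stood at 961 ± 247 against 1144 ± 352 CPM. In all 0 of 21174 rows passed with edgeR and 1017 had an unadjusted p under 0.05. The DESeq2 Wald test called 188 of 41575 rows, among them the 3 OR4X receptors, SLC5A3, FAM200B, C5H12orf45 and VARS. Of 15 chemosensory receptor rows 3 passed when adjusted over the family alone, a family chosen after its values were seen, and no family passed with camera. Detected rows numbered 24168 ± 713 against 23062 ± 2242 (exact permutation p = 0.486, n = 4), a difference of 1106.5 that was 83.6 without cleavage library D10 and 1844 without cleavage library B23.

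Between matched biopsies and whole oocytes no gene passed with edgeR. TUG1, a long noncoding RNA, stood at 31.4 ± 7.61 CPM in biopsies against 71.7 ± 11 in oocytes (log2 -1.19, edgeR quasi-likelihood adjusted p = 0.524). NSMCE3, a subunit of a DNA repair complex, stood at 43.8 ± 18.2 against 14.1 ± 4.24 CPM, and TCL1B, a kinase co-activator, at 52.4 ± 11 against 18.5 ± 10 CPM. WARS, which charges tryptophan tRNA, the histone H2AFX and ORAOV1 had higher means in biopsies, and SENP8, TROVE2 and ZNF569 lower ones. The olfactory receptor OR52I11 had 0 counts in biopsies and 80 in oocytes, at least 6.45-fold lower, and did not pass. H1FOO stood at 1000 ± 412 against 774 ± 235 CPM. In all 0 of 18540 rows passed with edgeR, and 1028 had an unadjusted p under 0.05. The DESeq2 Wald test called 194 of 37247 rows, NSMCE3, TCL1B, TUG1 and OR52I11 among them. With the pairs as a replicate block edgeR called 0 rows, with 1262 at an unadjusted p under 0.05. Zinc finger proteins, with a median of -0.32 over 39 rows, had a camera adjusted p of 0.0457, and adjusted p = 0.340 with an estimated correlation. Chemosensory receptors, with a median of -0.32 over 18 rows, had an adjusted p of 0.0322 by fry and of 0.227 by camera. Both families were written after a first fit had been seen. The median of all rows moved from -0.03 with TMM to 0.11 with library totals.

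Of the rows detected in a whole oocyte, 82.5 ± 1.54% were also detected in the biopsy of the same number (n = 4). Biopsies had 19825 ± 398 detected rows against 21611 ± 1049 in oocytes (exact permutation p = 0.0286, n = 4). This test is unpaired: by sign flips within the 4 pairs, the replicate block, the call was lost (exact p = 0.125, the smallest that 4 pairs allow). Without biopsy 3 or without biopsy 16 the unpaired exact permutation p was 0.0571. With libraries thinned to the smallest total the difference was -1030 rows (unpaired exact permutation p = 0.257). Each thinned biopsy still lay below its own oocyte: 20232 against 22255 for number 2 and 18597 against 18840 for 3. For numbers 6 and 16 the values were 19495 against 19753 and 18884 against 20480. Across genes, which are not independent replicates, the Pearson correlation of log2 CPM averaged 0.882 between a biopsy and its own oocyte and 0.855 between a biopsy and the other oocytes. The one-sided exact permutation p over 24 assignments was 0.0417, the smallest possible, and 0.0833 both with Spearman correlations and without a filter on low counts, where the difference was 0.0112. This test used the libraries by which the numbers had been accepted as pairs, so it is not independent of that check. Biopsies 2 and 16 correlated best with their own oocyte and biopsies 3 and 6 with oocyte 16. Different whole oocytes correlated with each other at a mean Pearson value of 0.912, above the mean of 0.882 between a biopsy and its own oocyte. Among different biopsies the mean was lower than both means between biopsies and oocytes. The value of 0.882 therefore does not show that a biopsy stands for its own oocyte.

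**Figure D2:**
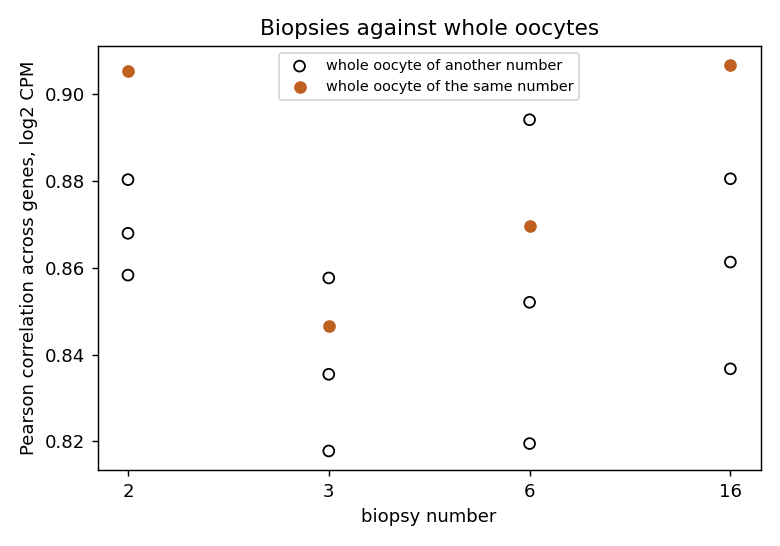
Pearson correlation across genes of log2 CPM between each biopsy and each whole oocyte of the matched set, filled for the same number and open for other numbers. Same-number values ran from 0.847 to 0.907.

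The signed log2 change, blastocyst minus cleavage, was higher in granulosa cells than in biopsies for the matrix protein ABI3BP (log2 difference 4.88, SE 0.85, edgeR quasi-likelihood adjusted p = 0.0104). It was also higher for the laminin chain LAMA2 (4.31, SE 0.82, edgeR adjusted p = 0.0121), NELL1, the germ cell proteins RNF17 and MORC1 and the kinase STK39. The same held for C10H14orf39, the scaffold MAGI2, GALNTL6 and the calcium channel RYR3. The signed change was lower in granulosa cells for RSKR (-8.98), C7H5orf30 (-5.63), FAM200A, MGC126945, RESTA, the collagen COL21A1, the transcriptional repressor REST (-2.07) and PDZK1. A lower signed change need not be a smaller difference between fates. COL21A1 had a log2 fold change of 1.02 in biopsies and -0.92 in granulosa cells, and passed in neither. Without granulosa library B23 the values of ABI3BP and LAMA2 were 6.10 and 5.60, and without granulosa B20 that of ABI3BP was 4.29. RSKR stood at -7.82, -8.37 and -10.61 without biopsy B20, B14 and B23 and at -10.35 without granulosa B21, and C7H5orf30 at -4.94, -7.14, -4.92 and -4.91 without biopsy B20, B14, D10 and D29. FAM200A, MGC126945, RESTA, COL21A1, REST and PDZK1 each lost the call without granulosa B20 and without granulosa D27, among other libraries. With the oocyte labels as a replicate block FAM200A, MGC126945, REST and PDZK1 no longer passed. In all 1948 of 28229 rows passed the edgeR interaction test, none of them among the 2789 NONCODE rows tested (2233 passed without these rows), 1793 with a higher value in granulosa cells and 155 with a lower one, and 1534 of the 1948 were also called in granulosa cells. The counts were 4751 higher and 920 lower with the DESeq2 Wald test, 3718 and 65 with library totals as the only scaling, 2242 and 254 with DESeq2 size factors, 1095 and 142 without a filter on low counts and 1329 and 72 with the replicate block. The total was 443 without granulosa library B20, 566 without D27, 697 without B14, 636 without D29 and 4955 without B23, and 3427 without biopsy D10. The lower calls numbered 33, 23, 29, 24 and 36 without granulosa B20, D27, B14, D29 and D10, 340 without granulosa B21, and 70, 53, 63, 57 and 100 without biopsy B20, B21, D24, D27 and B14. Without both granulosa libraries B20 and D27, chosen after seeing the data, the total was 45, with 43 higher and 2 lower.

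For first polar bodies the deposited table lists 34020 positions, 28585 on 29 numbered chromosomes, 1645 on X and 685 on the mitochondrial genome. Its values were not used here, and methylation was not compared between fates.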

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

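Tests of library depth and of oocyte fate were chosen after the result was seen, as were the fits without B20 and D27 and with a covariate, the shares of keratin-associated genes and the splits within pairs. In granulosa cells of the blastocyst group 4884 rows rose. Library depth alone does not account for this, since 8350.5 more rows were detected in the blastocyst group after thinning to the smallest total. A candidate explanation is background reads on rows whatever their expression, such as genomic DNA: of the excess over the cleavage mean in 4853 called rows, a median of 55.8% (quartiles 48.2 and 60.5%) lay in B20, against 58.5% for chemosensory receptor rows. A second family, 16 keratin-associated, cornified and defensin genes, had 47.4% in B20 (counting interval 44.6 to 50.2%) and 34.5% in D27 (31.8 to 37.1%, quartiles of the called rows 23.6 and 32.2%), so the 2 families differed by more than counting error. Oocyte fate cannot be told apart from that background, because the chemosensory level separates the groups, and with that level as a covariate edgeR called 0 rows (2499 at an unadjusted p under 0.05, and DESeq2 was not run with it). With the covariate the log2 fold change of TTLL11 went from 4.18 to 1.65 and that of SLC22A14 from 7.97 to 5.72.

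Among the 35 splits of the granulosa libraries only the real split, 1 of 35, gave as many edgeR calls (4964, highest other 0). That met the bound fixed beforehand, a share under 0.05. It is also the smallest share that 35 splits allow, and several such tests were run without correction. Neither chance nor a technical difference along the same split is therefore fully excluded. In cumulus cells 1 split of 35, the real one, gave as many rows at an unadjusted p under 0.05 (2249, highest other 1613). That count met the same bound, with the same limit. In biopsies 7 splits of 35 gave as many (1017, highest other 1601), so chance cannot be excluded. In the matched set 8 splits of 35 gave as many (1028, highest other 1712), but these ignore the pairs, and differences between oocytes enter the splits that keep pairs together. The splits that part all 4 pairs number 8, too few for a share under 0.05 (smallest 0.125), with 1028 in the real one and 1647 as the highest other, or 1262 and 2178 with the replicate block. For the interaction 1 split of 35 gave as many calls (1948, highest other 1), which met the bound of a share under 0.05 with the limit given for granulosa cells.

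The contrast of the fate groups differed between granulosa cells and biopsies in 1948 rows by the interaction test. Of these 1534 were also granulosa calls, and without granulosa libraries B20 and D27 the count was 45. The interaction was not fitted with the chemosensory level, so these rows are open to the same background reads and are not shown to be an effect of fate. Of 150 groups of 4 libraries checked for 1 library far from the others, 10 stood out, where chance gives about 1 in 20, or 7.5. Granulosa library B23 of the cleavage group had a count in 13.3% of chemosensory rows (others 2.53 to 3.51%), and D29 had 3.41% of counts on LOC identifiers (others 3.39%). HIST1H1A stood at 209 CPM in biopsy D24 (others 132 to 141), VARS at 6.78 in biopsy B21 (others 8.18 to 8.31), SLC5A3 at 42.2 in biopsy B23 (others 39.0 to 39.5) and TUG1 at 19.9 in matched biopsy 16 (others 35 to 35.3). HRASLS5 at 0.0658 CPM in granulosa B14, and ITIH6, MCHR2 and SLC22A14 at 0.0910 CPM in granulosa B23, rested on 1 count each against 0 in the other cleavage libraries.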

How the results depend on the processing

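Alternatives with library totals, a covariate or B20 and D27 left out were chosen after the data were seen, and unless stated the cause of a change was not tested. The DESeq2 Wald test was run on every row with a count. It called 188 of 41575 rows in biopsies, 11467 of 35243 in granulosa cells and 159 of 26278 in cumulus cells. In the matched set it called 194 of 37247 and in the interaction 5671 of 45487. Without a filter on low counts edgeR called 27 rows in biopsies, 7149 in granulosa cells, 183 in cumulus cells, 13 in the matched set and 1237 in the interaction. At adjusted p under 0.10 it called 10 in cumulus cells and 4067 in the interaction, and with library totals 3783 in the interaction. Without B20 and D27 it called 0 granulosa and 45 interaction rows, with fewer samples as part of the cause. With the chemosensory covariate it called 0 granulosa rows, with C5H12orf57 reversed to 0.17 and HEXDC to 0.47. Both values lay below the median of all rows in that fit, 0.86. Leaving out 1 library gave 2482 to 8131 calls in granulosa cells, 443 to 4955 in the interaction and 0 to 7 in cumulus cells, and 0 in biopsies and in the matched set with edgeR. The difference in detected rows ran from -203.75 to -29.75 in cumulus cells (exact permutation p = 0.0286 without library 9, and -0.5 after thinning), from 83.6 to 1844 in biopsies and from -2054 to -1285 in the matched set. There it was -1030 after thinning, and -1786 with sign flips in the replicate block, where the exact p of 0.125 is the smallest possible. The own-minus-other correlation was 0.0269, 0.0112 without a filter and 0.0243 with Spearman (exact one-sided p = 0.0833 for both), and 0.0199 to 0.0317 with 1 pair left out, where the smallest possible p is 0.167. Of the 1948 interaction calls of the unpaired fit, 1084 were also among the 1401 calls with the replicate block. Of the log2 values of named genes under alternatives other than leaving out 1 library, 393 kept direction and side of the threshold, 58 lost a call, 26 gained one and 2 reversed. No paired analysis was possible in cumulus cells because the numbers of the columns match no title number, the filter meant as stricter kept about as many rows, and the polar body alternatives were not run. Depth limits rows with few counts, such as SLC22A14.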

Other observations

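The test on FAM200B was chosen after the result was seen. Its levels here were scaled by TMM over all rows, without the filter on low counts, so they differ slightly from those above. FAM200B stood at 286 CPM in biopsy D10 and 122 in biopsy B23 (others 7.62 to 21.9), and at 73.8 and 77.4 CPM in the granulosa cells of these labels (others 2.54 to 9.71). Over the 8 labels Pearson's r was 0.853 (exact permutation p = 0.0241) and Spearman's rho 0.595 (exact permutation p = 0.132). Without D10 and B23 r was -0.207, so the relation rests on those samples, and as the gene was picked for this pattern the test decides nothing. By the labels and the series text, the biopsy and granulosa cells of 1 label come from the same follicle, and so the same animal. A candidate explanation is that the genotype of this animal sets the level in both cell types. Over all 7297 rows with enough counts, 20 correlated above 0.9, more than in 90 of 100 shuffled pairings (median 11, highest 29). This missed the 95 of 100 required beforehand, and the bound written beforehand would have counted it against an effect of the shared animal. That reading was set aside after the result was seen, because a count above the shuffled median excludes nothing. An effect of the shared animal on these levels therefore stays neither shown nor excluded.

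In the matched set, the biopsy minus oocyte log2 fold change was -0.21 for OR4X2B, -0.01 for OR4X16 and -0.16 for OR4X2. NONCODE identifiers took 4.21 to 9.27% of counts in matched oocytes and 4.56 to 6.96% in matched biopsies, but at most 0.000832% in granulosa cells and 0.00276% in cumulus cells, and whether the tables share an annotation is not given in the sources used here.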
